A study of Mus musculus with 16 samples.

How the data were processed

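Thymocytes of the earliest T cell stages were compared by microarray in 16 samples, 1 array each, from mice 4 weeks old. B6g7 mice are C57BL/6 animals that carry the NOD MHC haplotype H2g7, and NOD mice develop autoimmune diabetes. BDC mice carry the rearranged T cell receptor (TCR) genes of BDC2.5, a diabetogenic CD4 T cell clone, and mice without the transgene (non-Tg) have a polyclonal repertoire. After complement depletion of CD4 and CD8 cells, double-negative cells were sorted as DN2-3 (lineage-negative, CD25-positive) or DN4 (lineage-negative, CD44-negative, CD25-negative), per the labels. Strain, genotype and stage made 8 groups of 2 arrays. Every non-Tg array came from female mice, and each BDC group held 1 male and 1 female array.

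The authors extracted RNA with Trizol, labelled it with biotin and hybridized it to Affymetrix Mouse Gene 1.0 ST arrays. The deposited values were intensity values on a linear scale, made by the authors with RMA (background correction, quantile normalization of probes and median-polish summary) in Affymetrix Power Tools; the versions were not given in the sources used here. The deposited table had 25108 probe sets, with values from 5.82 to 21466. Values were put on the log2 scale without a pseudocount. Of the probe sets, 21157 had 1 gene symbol, 1341 had several and 2610 had none in the probe table. The brightest probe set by mean over all arrays was kept for each of 19531 genes. A gene was tested where its highest group mean reached the median of the named probe sets, 7.05 on the log2 scale or 132.9 on the linear scale, which left 10689 genes. The table gives no detection calls, and the number of arrays limits the precision. Gene names were checked against the GRCm38.p6 gene annotation, and chromosome order was used only for the MHC region.

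Differential expression was tested with limma 3.58.1 in R 4.3.3 (data.table, version 1.17.8, for reading), with lmFit on the 8 group means and eBayes, so that the pairs shared an estimate of the spread (8 residual and 5.06 prior degrees of freedom). The test was two-sided, with Benjamini-Hochberg adjustment over the genes of each comparison at a threshold of 0.05. Comparisons were NOD minus B6g7 in each genotype and stage and averaged over the 4 contexts, BDC minus non-Tg in each strain and stage and averaged over strains, DN4 minus DN2-3 averaged over the 4 contexts, and the interactions of strain with transgene, strain with stage and transgene with stage. Errors given with log2 fold changes are standard errors of this model, with 2 arrays per group. The p-values measure only the spread between these samples, since the labels do not say whether the samples of a group came from separate animals.

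Gene lists were tested with camera at a preset correlation of 0.01 where at least 5 members were tested, with adjustment over 304 tests of 19 lists; 127 were called, and 17 of these held with an estimated correlation. The tests with fry were run beside it. The lists covered key genes, gamma-delta T cell genes, the Notch pathway, early progenitor genes, the transition to double-positive cells, the TCR complex and proximal signalling, TCR-induced genes, the cell cycle, apoptosis, MHC and antigen presentation, the interferon response, candidate genes of diabetes loci, ribosome biogenesis and Myc targets, stress and immediate-early genes, and markers of mature T cells, B cells, myeloid and dendritic cells, NK and NKT cells, thymic stroma and erythroid cells. Genes of the T cell receptor loci and sex-linked genes were given by gene. Of 562 list entries 505 were matched to a probe set, and the other 57 were not analysed here.

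The comparisons, gene lists, test, filter and the rule for naming genes were chosen before the data were examined. The rule named up to 10 genes higher and 10 lower with the largest called change whose arrays did not overlap between the groups in any context compared (no overlap rule for interactions), up to 4 called members of each list, all key genes, and called TCR locus genes in the transgene comparisons. Predicted genes were left out of the largest changes. Other gene families were chosen after the results were seen and are given in the closing section.

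Alternatives chosen in the same way were no filter, a filter at an intensity of 120, every named probe set, quantile normalization again, centring of each array on its median, a replicate block, a random replicate block within strain and genotype, sex as a term, array weights, a trended and robust eBayes, only the arrays compared, a 2-fold minimum, and leaving out each array in turn. Leaving out the 4 male arrays, quantile normalization together with leaving out 1 array, a crossed replicate block, and raising signals to the highest Y-linked signal of a female array (5.98 log2), were added after the data were seen. Tested on simulated data made from the arrays, with 200 of 10689 genes changed, the comparison of BDC with non-Tg in DN4 recovered 95.5% of changes of 1.5-fold and 100% of those of 2-fold, with 9 false calls. The strain comparison in BDC DN4 recovered 76.1% and 98.5%, with 11 false calls. The strain by transgene interaction in DN4 recovered 29.9% and 89.6%, with 13 false calls. These rates hold for the simulated data only and may not carry over to the real arrays, whose groups differed in spread. The standard deviation of the replicate difference was 0.38 in NOD DN2-3 and 0.1315 in B6g7 DN2-3.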

Results

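Gene expression was measured in DN2-3 and DN4 thymocytes, the double-negative cells that precede CD4 and CD8 expression, from B6g7 and NOD mice with a polyclonal repertoire and from BDC2.5 transgenic mice on both backgrounds. Each of the 8 groups had 2 arrays. Median intensities ran from 123.1 to 138.2 over the 16 arrays, and replicates correlated across genes with r from 0.986 to 0.997. Replicate 1 of NOD DN2-3 stood apart: the ratio of its upper to its lower quartile was 6.82, and its median absolute log2 difference from its replicate was 0.25, against 0.07 to 0.13 in the other pairs. Both B6g7 DN4 arrays were also narrow, with quartile ratios of 7.60 and 7.46, while the other arrays had ratios from 8.30 to 10.3. Xist and the Y-linked genes matched the labelled sex on every array. Y-linked probe sets read 3.88 to 5.98 log2 on female arrays, where these genes are absent, and signals up to 5.98 were taken as not above background, a level chosen after the data were seen. A difference against a group at that level is given as "at least" the value with lower signals raised to it, with the adjusted p of the values as deposited. Xist read 5.70 to 6.73 log2 on the male arrays, so signals somewhat above 5.98 may also be background. Differences against such signals are given as measured.

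The first question was which genes differ between NOD and B6g7 in polyclonal and BDC2.5 thymocytes. Higher in NOD, averaged over the 4 contexts, were the zinc finger gene Zfp979 (at least 1.93 log2, adjusted p = 1.8e-12), not above background in any B6g7 group, and the transcript BC018473 (at least 4.21). Also higher were Gatm, an enzyme of creatine synthesis (at least 2.23), and Afdn, a junction protein (2.25 ± 0.06). NOD cells also had more H60b, a ligand of the NKG2D receptor (at least 1.21), Cd200, an inhibitory surface ligand (at least 1.32), and Odc1, the first enzyme of polyamine synthesis (1.25 ± 0.05). Lower in NOD were Trim12a, a member of the tripartite motif family, not above background in any NOD group (by at least 2.68, adjusted p = 9.2e-13), Abcb1b, a drug efflux transporter (by at least 2.74), Slamf1, a signalling receptor of lymphocytes (-1.94 ± 0.08), Cd72, a coreceptor best known in B cells (by at least 1.79), and Cd93 (-1.78 ± 0.05). The recombinase gene Rag1 was higher by 1.29 ± 0.12 and Ptcra, the pre-TCR alpha chain, by 0.82 ± 0.08, though neither passed in non-Tg DN2-3 cells. The costimulatory receptor gene Cd27 (-1.02 ± 0.06), the TCR signalling phosphatase gene Ptpn22 (-1.05 ± 0.07) and Sox13, a transcription factor of the gamma-delta lineage (-0.84 ± 0.06), were lower.

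By group, 37 of 46 cell cycle genes were higher in NOD on average and 1 was lower (39 and 2 adjusted over the list alone), among them Ccna2 (0.77 ± 0.04) and Cdc6 (0.66 ± 0.05). That list had adjusted p = 6.93e-09 with camera and adjusted p = 0.281 with an estimated correlation. Of 27 candidate genes of diabetes loci, 16 were lower and 2 higher (17 and 4 adjusted over the list alone), among them Slamf1, Cd93, Ptpn22 and Pparg (-0.87 ± 0.07). The call held at adjusted p = 0.0333 with an estimated correlation. Interferon response genes were lower in 17 of 28 and higher in 2 (18 and 2 adjusted over the list alone), for example Usp18 (-0.73 ± 0.09) and the RNA sensor Ifih1 (-0.71 ± 0.06), at adjusted p = 0.214 with an estimated correlation. Mature T cell markers were lower in 16 of 23 and higher in 2 (18 and 2 adjusted over the list alone), at adjusted p = 0.0621 with an estimated correlation. Gamma-delta T cell genes were lower in 11 of 17 and higher in 2, the same counts adjusted over the list alone, at adjusted p = 0.144 with an estimated correlation. MHC and antigen presentation genes were lower in 6 of 13 and none was higher, again the same adjusted over the list alone, with small changes such as B2m (-0.32 ± 0.08) and adjusted p = 0.281 with an estimated correlation. In all, 4451 of 10689 genes passed the limma test, 2861 higher and 1590 lower in NOD. The share higher was 64.3% and became 54.3% (2400 and 2021) after quantile normalization again. Without the 4 male arrays, which leaves 1 array in each BDC group, 2468 genes passed.

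In non-Tg DN2-3 cells 1130 genes differed, 534 higher and 596 lower in NOD. Besides Zfp979 (at least 2.27), the kinase gene Txk, which acts below the TCR, was higher (1.54 ± 0.13), as was Id2, an inhibitor of E proteins (1.00 ± 0.14), and the peptide transporter gene Slc15a2, not above background in NOD, was lower by at least 3.47 (adjusted p = 5.6e-04). Rag1, Ptcra, Cd5 and Cd69 did not pass here, with changes of -0.33 ± 0.24, 0.08 ± 0.16, -0.03 ± 0.10 and -0.01 ± 0.19. Only 4 gamma-delta T cell genes were lower (6 adjusted over the list alone, with 2 higher), including the chemokine receptor gene Ccr9 (-1.01 ± 0.16), and the list had adjusted p = 0.342 with an estimated correlation. After centring of each array on its median the split was 318 higher and 639 lower. The count was 388 without B6g7 DN2-3 replicate 1, 508 without its replicate 2 and 4742 without NOD DN2-3 replicate 2. It was 81 with only the arrays compared, 226 with array weights and 380 without the 4 male arrays.

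In BDC DN2-3 cells 982 genes differed, 377 higher and 605 lower in NOD. The T cell progenitor factors Hhex (-1.24 ± 0.13), Erg (-1.01 ± 0.10), Spi1 (-0.99 ± 0.17) and Lyl1 (-0.88 ± 0.10) were lower, within 6 of 17 early progenitor genes that were lower and none higher, the same adjusted over the list alone. This list held at adjusted p = 0.0452 with an estimated correlation. Rag1 (1.37 ± 0.24) and Ptcra (0.87 ± 0.16) were higher, and Cd5, a negative regulator of TCR signalling, was lower (-0.88 ± 0.10). Sox13 (-0.98 ± 0.11) and the granzyme gene Gzmb (-1.30 ± 0.14) were lower and Zbtb16, the factor of innate-like T cells, was higher (1.10 ± 0.15), in a gamma-delta list with 8 of 17 lower and 1 higher (10 and 3 adjusted over the list alone) and adjusted p = 0.157 with an estimated correlation. Centring on the medians gave 244 higher and 616 lower. The count was 1679 without either NOD DN2-3 replicate 1 or 2. It was 608 and 546 without BDC/B6g7 DN2-3 replicates 1 and 2, 525 and 447 without BDC/NOD DN2-3 replicates 1 and 2. It was 1505 with only the arrays compared, 1710 with array weights and 133 without the 4 male arrays.

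In non-Tg DN4 cells 2004 genes differed, 1496 higher and 508 lower in NOD. Scd1, a fatty acid desaturase, was higher (2.63 ± 0.26, adjusted p = 3.9e-05), as were the signalling inhibitor Spry1 (1.78 ± 0.27), Ptcra (0.84 ± 0.16), Cd4 (0.86 ± 0.14), Id3 (0.81 ± 0.13) and the early response factor Egr1 (0.74 ± 0.16). The CD8 genes Cd8b1 (-1.64 ± 0.22) and Cd8a (-0.57 ± 0.18), the costimulatory gene Icos (-0.87 ± 0.14) and Il7r, the interleukin 7 receptor (-0.40 ± 0.11), were lower. Diabetes locus genes were lower in 8 of 27 and higher in 2, the same adjusted over the list alone. They held at adjusted p = 0.0381 with an estimated correlation, though their median of -0.07 became 0.01 after centring. The median of all genes was 0.13 in this comparison and 0.02 after quantile normalization again, so changes of this size depended on the scaling. The split was 734 higher and 619 lower with that normalization and 2370 and 325 after centring. The count was 4379 without either NOD DN2-3 replicate 1 or 2, which take no part in the comparison. It was 571 without B6g7 DN4 replicate 1, 914 and 435 without NOD DN4 replicates 1 and 2, 3012 with array weights and 417 without the 4 male arrays.

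The strain comparison in BDC DN4 cells gave 4387 genes, 2756 higher and 1631 lower in NOD. Rag1 (3.26 ± 0.24, adjusted p = 5.0e-07), the semaphorin receptor gene Nrp1 (3.02 ± 0.16), Ptcra (1.47 ± 0.16), Cd8a (1.58 ± 0.18) and Cd4 (0.74 ± 0.14) were higher. The nucleotide hydrolase Samhd1 (-3.29 ± 0.17), the cytokine receptor chain Il2rb (-2.70 ± 0.14), Icos (-2.13 ± 0.14), the egress receptor S1pr1 (-1.78 ± 0.12) and Sox13 (-1.45 ± 0.11) were lower. Cell cycle genes were higher in 42 of 46 and lower in 1, the same adjusted over the list alone, with Ccne2 (1.95 ± 0.17), Tyms (1.71 ± 0.09) and Ccna2 (1.67 ± 0.09) and adjusted p = 0.157 with an estimated correlation. Genes of ribosome biogenesis and Myc were higher in 24 of 30 and lower in 1 (25 and 1 adjusted over the list alone), with Srm (1.51 ± 0.22) and Gnl3 (1.32 ± 0.09), at adjusted p = 0.281 with an estimated correlation. Mature T cell markers were lower in 18 of 23 and higher in 2, also adjusted over the list alone, and held at adjusted p = 0.0404 with an estimated correlation. Diabetes locus genes were lower in 14 of 27 and none was higher (14 and 1 adjusted over the list alone), which held at adjusted p = 0.0298 with an estimated correlation. Proximal TCR signalling genes were lower in 15 of 28 and higher in 3 (19 and 3 adjusted over the list alone), among them Ptpn22 (-1.53 ± 0.13), Txk (-1.34 ± 0.13) and the TCR zeta chain Cd247 (-1.03 ± 0.12), at adjusted p = 0.18 with an estimated correlation. Quantile normalization again gave 2362 higher and 2165 lower, and 1731 genes passed without the 4 male arrays.

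Across the 4 contexts, 117 genes were higher in NOD every time, where independent lists of these sizes give 0.68, and 121 were lower every time against 0.245, out of 5649 genes called in any context. Of 88 tested genes in the MHC region, between H2-K1 and H2-M3, 1 was among these 238. In 9 genes lower in NOD every time that had other probe sets on the array, 8 of the 13 other probe sets showed at least 0.5 of the log2 change. Another 174 genes were called higher in some contexts and lower in others. Strain effects in non-Tg and BDC cells correlated across genes, which are not independent replicates, with r = 0.602 in DN2-3 and 0.463 in DN4, and 8 and 84 genes were called in opposite directions where chance gives 51.25 and 359.3.

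The transgene comparisons address what an early rearranged TCR does to cells that would otherwise signal through the pre-TCR. They compare sorted populations, so they cannot separate a change within cells from a different mix of cells. In DN2-3 cells, Etv5, a transcription factor of gamma-delta cells, was higher in BDC mice by 3.92 ± 0.07 log2 (adjusted p = 6.8e-13), as were the oligopeptide transporter Slc15a1 (at least 3.05), Igfbp4 (3.05 ± 0.08), the adhesion receptor Cd2 (2.55 ± 0.08), the Src kinase Blk (2.35 ± 0.10) and the granzyme gene Gzma (2.00 ± 0.10). The TCR pathway genes Pdcd1 (1.78 ± 0.07), Cd5 (1.25 ± 0.07), Zap70 (1.20 ± 0.07) and Nr4a1 (1.13 ± 0.25) rose. Mean Nr4a1 went from 11.85 to 12.60 in B6g7 and from 10.85 to 12.35 in NOD. The NOD DN2-3 arrays disagreed on this gene, with a standard deviation of 1.18. The surface enzyme Bst1 (-4.09 ± 0.10, adjusted p = 8.8e-12), Ly6d (-2.55 ± 0.13), the recombinase genes Rag2 (by at least 2.15) and Rag1 (-2.37 ± 0.17), Ptcra (-1.45 ± 0.11), Notch3 (-1.49 ± 0.15), Il7r (-0.86 ± 0.08) and the activation marker Cd69 (-1.54 ± 0.13) fell. All 3 tested TCR locus genes were lower, also adjusted over the list alone: the delta variable gene Trdv2-2 (-2.47 ± 0.11), Trbv1 (-1.08 ± 0.12) and Trav13-5 (-0.38 ± 0.10).

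Of 17 gamma-delta T cell genes, 11 rose in BDC DN2-3 cells and 1 fell (13 and 2 adjusted over the list alone), including Cd163l1 (1.82 ± 0.08), a scavenger receptor of these cells, and the list had adjusted p = 0.157 with an estimated correlation. Cell cycle genes rose in 44 of 46 and fell in 1, the same adjusted over the list alone, with the mitotic genes Birc5 (1.07 ± 0.08) and Kif20a (0.94 ± 0.14), at adjusted p = 0.177 with an estimated correlation. Ribosome biogenesis and Myc genes rose in 23 of 30 and fell in 1 (25 and 1 adjusted over the list alone), at adjusted p = 0.344 with an estimated correlation. Interferon response genes fell in 18 of 28 and none rose (19 and 0 adjusted over the list alone), with Ifit1 (by at least 1.38) and Zbp1 (-1.08 ± 0.09), at adjusted p = 0.157 with an estimated correlation. Genes of the transition to double-positive cells fell in 15 of 26 and rose in 5 (16 and 6 adjusted over the list alone), at adjusted p = 0.177 with an estimated correlation. Notch pathway genes fell in 7 of 17 and rose in 1, also adjusted over the list alone, at adjusted p = 0.427 with an estimated correlation. TCR-induced genes rose in 13 of 29 and fell in 6, the same adjusted over the list alone, and this list was not called (adjusted p = 0.254). In total 5245 genes passed, 3180 higher and 2065 lower in BDC cells. The split was 2748 and 2484 after quantile normalization again and 3689 and 1548 after centring. Without the 4 male arrays 2611 passed, and a term for sex kept the count within 1.5 times.

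Within strains, 3138 genes passed in B6g7 DN2-3 cells (1800 higher, 1338 lower) and 3808 in NOD DN2-3 cells (2303 higher, 1505 lower). Both strains shared 1183 higher and 896 lower genes, against 387.8 and 188.4 by chance, 17 were called in opposite directions, and effects correlated with r = 0.773 across genes. Rag1 fell by 3.21 ± 0.24 in B6g7 and by 1.52 ± 0.24 in NOD, while Etv5 rose by 4.14 ± 0.10 and 3.70 ± 0.10. Early progenitor genes fell in 10 of 17 in NOD and none rose (11 and 0 adjusted over the list alone), with Mef2c (-1.19 ± 0.16) and Id2 (-1.15 ± 0.14), which held at adjusted p = 0.0333 with an estimated correlation. In B6g7 4 of that list fell and 3 rose, the same adjusted over the list alone, without a call (adjusted p = 0.596). In B6g7 the split was 1555 higher and 1670 lower after quantile normalization again and 1954 and 980 after centring. In NOD the split was 2705 higher and 1086 lower after centring. There the count was 5784 without NOD DN2-3 replicate 2, 2017 and 2157 without BDC/NOD DN2-3 replicates 1 and 2. It was 297 with only the arrays compared, 1228 with array weights and 855 without the 4 male arrays. In B6g7 it was 1821 and 1625 without B6g7 DN2-3 replicates 1 and 2, 1889 without BDC/B6g7 DN2-3 replicate 2 and 977 without the 4 male arrays.

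In DN4 cells 6367 genes differed between BDC and non-Tg mice, 3072 higher and 3295 lower in BDC cells. After centring 3216 were higher and 2861 lower, so which side was larger depended on the scaling. The protease gene Cpa3, best known in mast cells, rose by 5.09 ± 0.14 log2 (adjusted p = 9.3e-12), Slc15a1 by at least 4.63, the chemokine receptor Ccr8 by 4.89 ± 0.12, the integrin Itgae by 4.20 ± 0.12, Blk by 4.19 ± 0.10, Etv5 by 4.00 ± 0.07, Cd163l1 by 3.84 ± 0.08 and S1pr1 by 3.63 ± 0.09. Sox13 (2.14 ± 0.08), Cd69 (1.60 ± 0.13), Nr4a1 (1.44 ± 0.25) and the survival gene Bcl2 (1.87 ± 0.08) rose as well. Bst1 (-3.02 ± 0.10), Trdv2-2 (-2.82 ± 0.11), Ly6d (-2.79 ± 0.13), Rag2 (by at least 1.93), Rag1 (-2.25 ± 0.17), Cd8a (-1.45 ± 0.12) and Ptcra (-1.15 ± 0.11) fell. Il7r (0.04 ± 0.08) and Id3 (-0.07 ± 0.09) did not pass.

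Gamma-delta T cell genes rose in 12 of 17 in BDC DN4 cells and fell in 1, the same adjusted over the list alone, with a median of 1.49 and adjusted p = 0.0907 with an estimated correlation. Mature T cell markers rose in 19 of 23 and fell in 2, also adjusted over the list alone, with Gimap4 (3.37 ± 0.08) and Ms4a4b (at least 2.13), and held at adjusted p = 0.0381 with an estimated correlation. Proximal TCR signalling genes rose in 21 of 28 and fell in 4, unchanged when adjusted over the list alone, with Txk (2.22 ± 0.09) and Prkcq (2.01 ± 0.06), at adjusted p = 0.18 with an estimated correlation. TCR-induced genes rose in 23 of 29 and fell in 3, the same adjusted over the list alone, with Pdcd1 (2.76 ± 0.07) and Irf4 (1.85 ± 0.13), at adjusted p = 0.171 with an estimated correlation. Diabetes locus genes rose in 17 of 27 and fell in 4, the same adjusted over the list alone, with Tlr1 (at least 2.54) and Rgs1 (2.61 ± 0.21), and held at adjusted p = 0.0377 with an estimated correlation. Interferon response genes rose in 13 of 28 and fell in 2, also adjusted over the list alone, with Usp18 (1.45 ± 0.12) and Irf7 (1.19 ± 0.12), at adjusted p = 0.427 with an estimated correlation. Cell cycle genes fell in 41 of 46 and rose in 2, the same adjusted over the list alone, with Ccne2 (-1.80 ± 0.12) and Bub1 (-1.39 ± 0.07), at adjusted p = 0.18 with an estimated correlation. Ribosome biogenesis and Myc genes fell in 21 of 30 and rose in 3, also adjusted over the list alone, at adjusted p = 0.396 with an estimated correlation. Apoptosis genes rose in 8 of 19 and fell in 1 (6 and 1 adjusted over the list alone), with Cflar (1.20 ± 0.08) higher and Bid (-1.23 ± 0.06) lower, and the list was not called (adjusted p = 0.182). The 15 key genes were not called as a set in this comparison (adjusted p = 0.776), with 7 higher and 6 lower both over all genes and adjusted over the list alone.

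**Figure D1:**
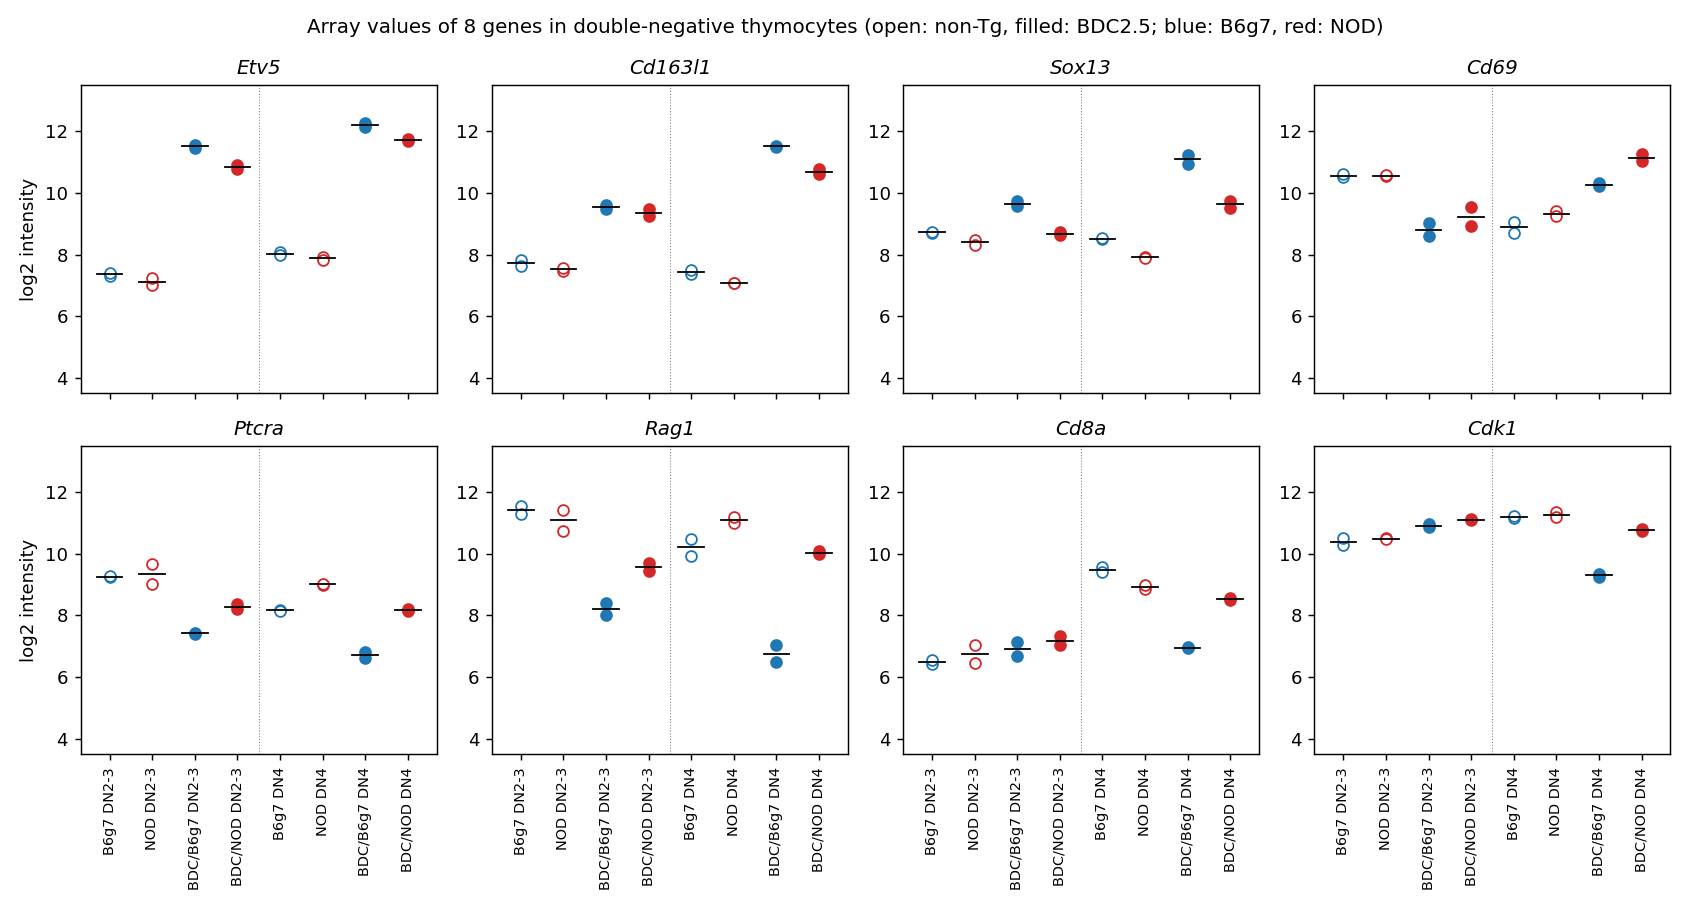
Log2 intensity (vertical axis) of 8 genes on each of the 16 arrays, by group, with open circles for non-Tg, filled circles for BDC, blue for B6g7, red for NOD and a black line for the mean of the 2 arrays. Etv5 was at 10.76 or above on every BDC array and at 8.075 or below on every non-Tg array, and Cdk1 was lowest on the BDC/B6g7 DN4 arrays, at 9.34 and 9.25.

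Separately, 6336 genes passed in B6g7 DN4 cells (3213 higher, 3123 lower), 1665 of them by at least 2-fold, and 2709 in NOD DN4 cells (1132 higher, 1577 lower), 278 of them by at least 2-fold. After centring the B6g7 split was 3547 higher and 2526 lower. Shared calls were 1087 higher and 1409 lower against 340.3 and 460.8 by chance, 19 genes went opposite ways, and r was 0.837 across genes. In B6g7 the cell cycle list fell in 42 of 46 with a median of -1.35 and rose in 2 (42 and 3 adjusted over the list alone). In NOD it fell in 23 with a median of -0.41 (30 adjusted over the list alone). The adjusted p was 0.171 in B6g7 and 0.292 in NOD with an estimated correlation. Gamma-delta genes rose in 12 of 17 in both strains, and the call held in NOD at adjusted p = 0.0377 and was lost in B6g7 at adjusted p = 0.112, both with an estimated correlation. Adjusted over the list alone 13 rose in NOD and 12 in B6g7. NK and NKT cell markers were called as higher in NOD too, with a median of 0.27 and 4 of 11 higher and 1 lower (5 and 1 adjusted over the list alone), at adjusted p = 0.18 with an estimated correlation. The NOD count was 1444 and 1710 without NOD DN4 replicates 1 and 2, 1353 and 1573 without BDC/NOD DN4 replicates 1 and 2. It was 4098 with only the arrays compared, 4491 with array weights and 613 without the 4 male arrays.

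From DN2-3 to DN4, averaged over the 4 contexts, the sort marker gene Il2ra, which encodes CD25, fell by 2.95 ± 0.06 log2 (adjusted p = 3.0e-12). The cytokine signalling inhibitor Socs2 (by at least 2.75), Kit, the stem cell factor receptor (-1.20 ± 0.07), Cd44 (-1.34 ± 0.05), Bcl2 (-0.99 ± 0.05) and Il7r (-0.93 ± 0.05) fell too. Ccr8 (at least 2.61), the Ikaros family factor Ikzf3 (2.23 ± 0.10), Cd8b1 (2.02 ± 0.11), Cd2 (1.72 ± 0.05) and Cd8a (1.64 ± 0.09) rose. Mean Cd8a went from 6.49 to 9.48 in B6g7 but only from 6.91 to 6.95 in BDC/B6g7. Early progenitor genes fell in 14 of 17 and rose in 1, the same adjusted over the list alone, with Erg (-1.83 ± 0.05) and Spi1 (by at least 1.27), and held at adjusted p = 0.008 with an estimated correlation. Notch pathway genes fell in 12 of 17 and none rose, also adjusted over the list alone, with Dtx1 (-0.97 ± 0.13) and Nrarp (-0.84 ± 0.08), at adjusted p = 0.171 with an estimated correlation. Genes of the transition to double-positive cells rose in 14 of 26 and fell in 6, the same adjusted over the list alone, at adjusted p = 0.177 with an estimated correlation.

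The stage test called 2940 genes, 1437 higher and 1503 lower in DN4, and only 1107 of them changed in the same direction in all 4 contexts, so the average joins unlike changes. After centring on the medians 1597 were higher and 1087 lower. The count was 4740 without NOD DN2-3 replicate 1 and 1113 without the 4 male arrays.

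**Figure D2:**
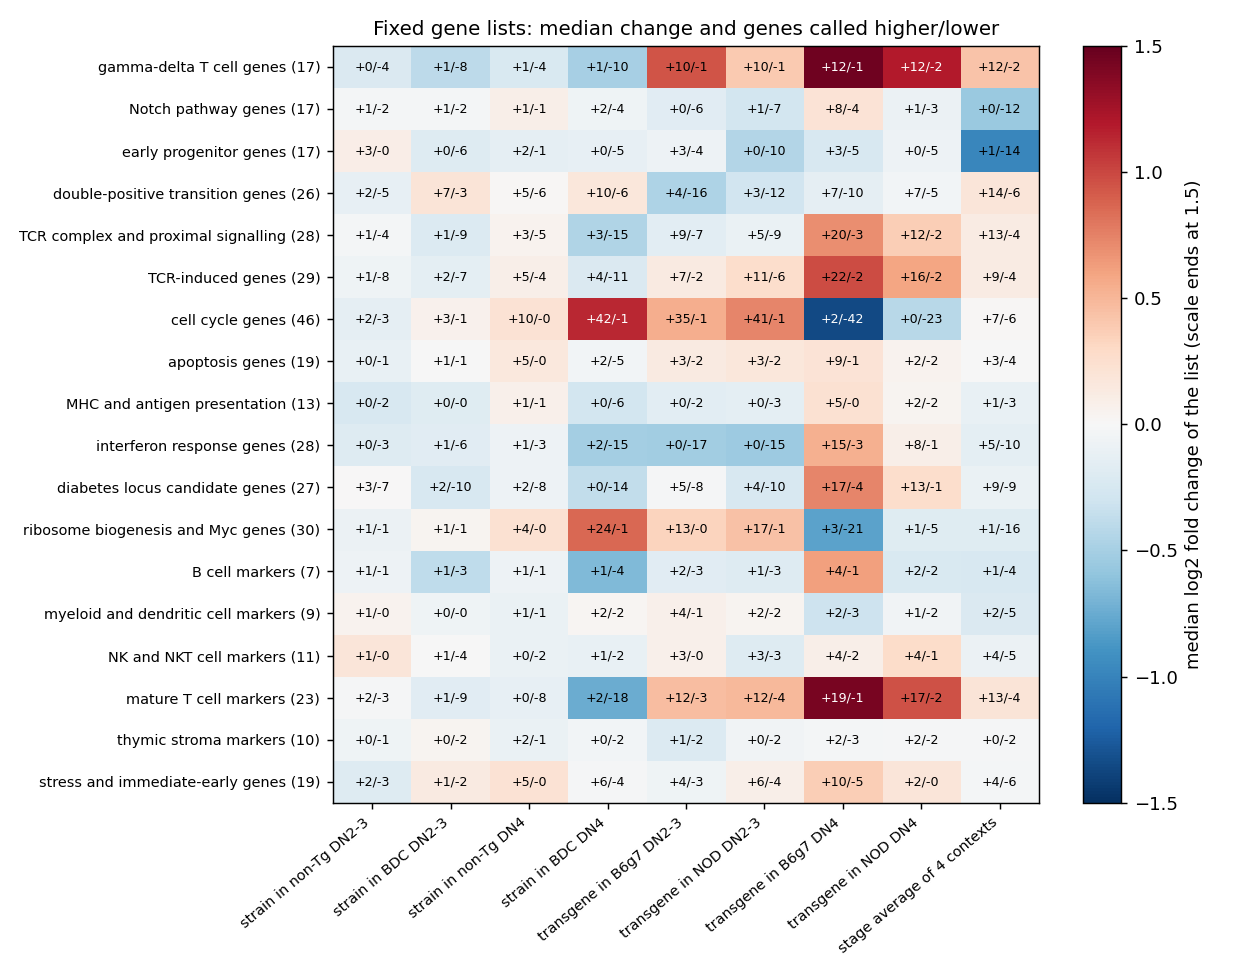
Median log2 fold change (colour, from -1.5 in blue to 1.5 in red) of each fixed gene list in 9 comparisons, with the number of tested members after the name and the numbers called higher and lower in each cell. Cell cycle genes go from 2 higher and 42 lower for the transgene in B6g7 DN4 to 42 higher and 1 lower for the strain in BDC DN4. Both comparisons use the BDC/B6g7 DN4 arrays, with opposite sign, so these counts are not independent. Several medians near 0, such as that of diabetes locus genes for the strain in non-Tg DN4, change sign with the scaling.

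Whether the transgene effect differs between the strains was tested by interactions. In DN2-3 cells 123 genes passed, 35 with a higher and 88 with a lower transgene effect in NOD. The interaction was 1.69 ± 0.34 for Rag1 (adjusted p = 3.3e-02) and 1.53 ± 0.23 for Ccr9, and -3.23 ± 0.32 for the glycosyltransferase B4galnt2 (adjusted p = 7.9e-04), -1.56 ± 0.20 for Gzmb, -1.38 ± 0.19 for Txk, -1.36 ± 0.19 for Hhex, -0.92 ± 0.13 for Erg and -0.85 ± 0.14 for Cd5. For Ptcra (0.79 ± 0.22, adjusted p = 1.3e-01) and Sox13 (-0.66 ± 0.16, adjusted p = 7.8e-02) no difference was called. Early progenitor genes had a lower effect in NOD in 3 of 17 and a higher one in none (10 and 0 adjusted over the list alone), with a median of -0.59, which held at adjusted p = 0.0185 with an estimated correlation. Lower effects in NOD were also called for 3 lists of other cells, each lost with an estimated correlation. These were B cell markers (median -0.31, 0 of 7 passed, 1 higher and 3 lower adjusted over the list alone, adjusted p = 0.273 with an estimated correlation) and myeloid and dendritic cell markers (median -0.19, 0 of 9 both ways, adjusted p = 0.171 with an estimated correlation). The last was NK and NKT cell markers, with a median of -0.19 and 2 of 11 lower (1 higher and 5 lower adjusted over the list alone), Gzmb among them, and adjusted p = 0.157 with an estimated correlation. Leaving out any of the 8 DN2-3 arrays moved the count by over 1.5 times: to 59 and 60 for B6g7 replicates 1 and 2, 265 and 2744 for NOD, 56 and 69 for BDC/B6g7, and 58 and 59 for BDC/NOD. It was 30 with only the arrays compared, 36 with array weights and 4 without the 4 male arrays.

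In DN4 cells 2152 genes had a transgene effect that differed between the strains, 983 positive and 1169 negative. Of these, 2089 were called for the transgene in B6g7, and in 2073 the interaction had the sign opposite to the B6g7 effect, so that the change was smaller or reversed in NOD. Opposite signs are favoured by construction, since the interaction subtracts the B6g7 effect. The fall of Cd8b1 was -3.06 ± 0.22 in B6g7 with an interaction of 2.78 ± 0.31 (adjusted p = 8.6e-05), and that of Rag1 was -3.44 ± 0.24 in B6g7 and -1.05 ± 0.24 in NOD with an interaction of 2.38 ± 0.34. Samhd1 rose by at least 4.16 in B6g7. Il2rb rose by 3.15 ± 0.14 in B6g7 and 0.41 ± 0.14 in NOD with an interaction of -2.74 ± 0.19 (adjusted p = 7.0e-06), and S1pr1 by 4.52 ± 0.12 and 2.74 ± 0.12 with -1.78 ± 0.17. Sox13 (-0.85 ± 0.16), Pdcd1 (-1.01 ± 0.15) and Id3 (-0.68 ± 0.18) also had lower effects in NOD, while Cd69 (0.43 ± 0.27) and Ptcra (0.63 ± 0.22) did not pass. Cell cycle genes had a positive interaction in 35 of 46 and a negative one in none (39 and 1 adjusted over the list alone), at adjusted p = 0.128 with an estimated correlation. Proximal TCR signalling genes were negative in 12 of 28 and positive in 1 (14 and 1 adjusted over the list alone), at adjusted p = 0.253 with an estimated correlation. After centring the split was 660 positive and 1398 negative. The count was 3734 without either NOD DN2-3 replicate 1 or 2. It was 1305 without NOD DN4 replicate 2, 1401 without BDC/B6g7 DN4 replicate 1, 1395 and 1335 without BDC/NOD DN4 replicates 1 and 2, and 3305 with only the arrays compared, 3436 with array weights and 321 without the 4 male arrays.

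**Figure D3:**
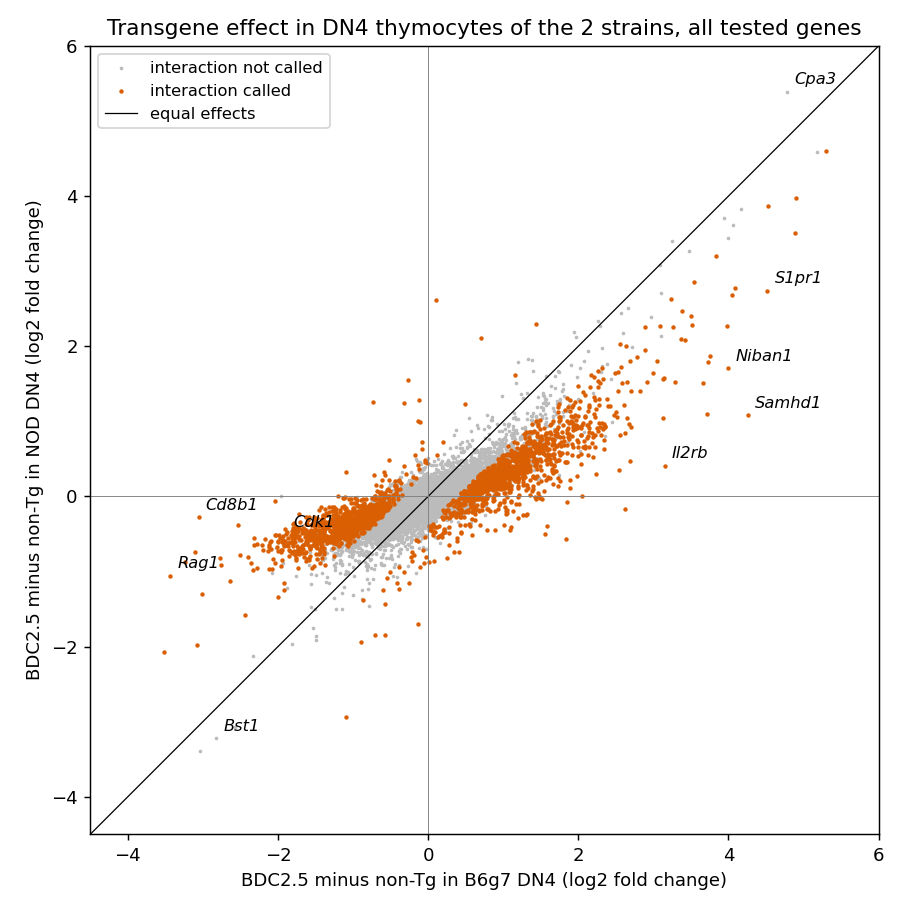
Log2 fold change of BDC against non-Tg in DN4 cells of B6g7 (horizontal axis) and NOD (vertical axis) for the 10689 tested genes, orange where the strain by transgene interaction was called (2152 genes) and grey where it was not, with a black line of equal effects. In 2073 of the orange genes the NOD effect was smaller than the B6g7 effect or reversed, and points of this kind lie on the side of the line nearer to a NOD effect of 0.

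The strain difference itself changed with stage in 2329 genes, 1877 with a higher and 452 with a lower NOD effect in DN4. Rag1 (1.55 ± 0.24, adjusted p = 1.5e-03), the nucleotide enzyme Rrm2 (1.43 ± 0.20), Uhrf1 (1.30 ± 0.17), E2f1 (1.28 ± 0.18), Id3 (0.70 ± 0.13) and Ptcra (0.68 ± 0.16) shifted upward. Icos (-1.85 ± 0.14, adjusted p = 7.0e-05), Txk (-1.49 ± 0.13), S1pr1 (-1.35 ± 0.12) and Il7r (-0.58 ± 0.11) shifted downward. Cell cycle genes were positive in 43 of 46 and negative in none (44 and 0 adjusted over the list alone), at adjusted p = 0.157 with an estimated correlation. Diabetes locus genes were negative in 6 of 27 and positive in 1 (6 and 2 adjusted over the list alone), which held at adjusted p = 0.0333 with an estimated correlation. Mean and median were positive and the test negative for the Notch, double-positive transition, TCR-induced and MHC lists here, none of them called. The proximal TCR signalling list was called as lower (adjusted p = 0.376 with an estimated correlation) with a mean of -0.05 and a median of 0.01, which was -0.12 after quantile normalization again. The median of all genes was 0.13 and became 0.01 after quantile normalization again, with 906 higher and 592 lower (1498 genes), and centring gave 2627 and 238. The count was 5474 without NOD DN2-3 replicate 2, 1289 without B6g7 DN2-3 replicate 1, 1481 and 1393 without BDC/NOD DN2-3 replicates 1 and 2. It was 1279 without NOD DN4 replicate 2, 1380 without BDC/B6g7 DN4 replicate 2, 1197 without BDC/NOD DN4 replicate 2 and 26 without the 4 male arrays.

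The transgene effect differed between the stages in 6177 genes, 2812 with a higher and 3365 with a lower effect in DN4, and 2211 genes were called in opposite directions in the 2 stages, where chance gives 1574. Effects in DN2-3 and DN4 correlated across genes with r = 0.0331. The interaction was 4.98 ± 0.20 for Cpa3 (adjusted p = 1.6e-09), 4.26 ± 0.16 for Ccr9, 3.14 ± 0.19 for Cd69, 1.53 ± 0.11 for Sox13, 0.90 ± 0.11 for Il7r and 0.83 ± 0.16 for Egr1. It was -2.78 ± 0.22 for Cd8b1, -2.30 ± 0.09 for Ccne1, -1.88 ± 0.18 for Cd8a and -1.02 ± 0.13 for Id3, and Rag1 (0.12 ± 0.24) and Ptcra (0.31 ± 0.16) did not pass. Cell cycle genes were negative in 44 of 46 and positive in 1, the same adjusted over the list alone, at adjusted p = 0.157 with an estimated correlation. Interferon response genes were positive in 22 of 28 and negative in 2, also adjusted over the list alone, at adjusted p = 0.177 with an estimated correlation. Diabetes locus genes were positive in 19 of 27 and negative in 2, the same adjusted over the list alone, which held at adjusted p = 0.0332 with an estimated correlation.

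Markers of other cells that a sort could hold moved in mixed directions in BDC DN4 cells. B cell markers were higher in 4 of 7 and lower in 2 (4 and 3 adjusted over the list alone), with Blk, which gamma-delta cells also express, and Cd37 (1.84 ± 0.14) higher and Spib (-1.09 ± 0.14) lower. Myeloid and dendritic cell markers were higher in 2 of 9 and lower in 3, also adjusted over the list alone, with Cx3cr1 (1.44 ± 0.07) higher and Bst2 (-0.57 ± 0.09) lower. NK and NKT cell markers were higher in 4 of 11 and lower in 2, the same adjusted over the list alone, with Nkg7 (3.20 ± 0.09) higher and Tbx21 (-0.92 ± 0.11) lower. Thymic stroma markers were higher in 2 of 10 and lower in 2 (2 and 1 adjusted over the list alone), with Pdgfrb (1.36 ± 0.11) and Pecam1 (1.33 ± 0.09) higher, and stress and immediate-early genes were higher in 10 of 19 and lower in 5, the same adjusted over the list alone. The median and mean were -0.13 and 0.06 for myeloid cells, where the test was negative, and -0.08 and 0.17 for stroma, where it was positive. None of these 5 lists was called in that comparison, with adjusted p from 0.146 for NK and NKT cells and 0.252 for B cells to 0.858 for stroma and 0.948 for myeloid cells, and 0.3 for stress genes. Of 2 tested erythroid markers neither was called over all genes or adjusted over the list alone. Besides the calls given with the strain by transgene interaction in DN2-3 and the transgene in NOD DN4, B cell markers were called as lower in NOD BDC DN4 cells (4 of 7 lower, 1 higher) and in the DN4 strain by transgene interaction (4 lower, none higher), and as higher in the transgene by stage interaction (6 higher, none lower). NK and NKT cell markers were called as lower for strain in non-Tg DN4 cells (2 of 11 lower, 3 adjusted over the list alone) and for strain by stage (4 lower and 1 higher, 5 and 1 adjusted over the list alone). The B cell counts were the same adjusted over the list alone. In this order the 5 had adjusted p = 0.18, 0.228, 0.165, 0.137 and 0.112 with an estimated correlation.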

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

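The tests of other splits, of the share of strain differences higher in NOD, of the MHC region, of implied shares of cells, of the interaction after quantile normalization and of the cell cycle median were chosen after the results were seen. The test within BDC arrays replaced an earlier test of the same pattern that was void by design.

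Effects that differed between groups, by an interaction test in limma, covered 123 genes for the strain and transgene in DN2-3, 2152 in DN4, 2329 for strain and stage and 6177 for transgene and stage. The transgene effect on Cd69 was higher in DN4 than in DN2-3 by 3.14 log2, and for Cd8a the same interaction was -1.88. Outside the named genes, 872 of 1995 probe sets with no gene symbol or several differed between BDC and non-Tg DN4 cells, 269 higher and 603 lower.

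Chance was tested by refitting other splits. For the strain average 1 of 100 splits, the real one, called as many genes (4451, highest other 3759). For the transgene by stage interaction it was also 1 of 100 (6177, highest other 4879). For the stage average it was 2 of 100 (2940, highest other 4538) and for the strain by stage interaction 3 of 100 (2329, highest other 3162). Each split exchanged the labels of 1 factor within the other 2. These ranks therefore speak, at 0.05, only against no effect of that factor in any context. They cannot exclude chance for an average or an interaction, since such splits can carry real effects of other comparisons into the tested one. For example, exchanging the stage labels of all BDC arrays turns the stage average into a multiple of the transgene by stage interaction. Which effects raised the highest counts was not tested. Without other terms, the transgene split was 1 of 35 in DN2-3 (3104 genes, highest other 244) and 1 of 35 in DN4 (3698, highest other 483), and in both stages the highest other split was the one by strain.

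The 1st pattern weighed was the strain differences called the same way in all 4 contexts. Probes that mismatch NOD alleles lower the signal of NOD arrays. Of the genes in this pattern 49.16% were higher in NOD (exact binomial interval 42.64 to 55.7), which argues against mismatch as the whole cause. Of all genes called in the strain average 64.28% were higher, above that interval, which goes with mismatch as part of the cause. That share became 54.3% after quantile normalization again, within the interval, so a part played by mismatch stays open. For the genes lower in NOD, 61.54% of other probe sets (8 of 13, interval 31.58 to 86.14) showed at least 0.5 of the change. These 13 came from 9 genes, several of them from Tns1, so they are not independent. Mismatch and lower expression cannot be told apart with so few probe sets. Local DNA differences remain possible: 1.136% of tested genes in the MHC region belonged to the pattern (interval 0.02877 to 6.169) against 2.24% elsewhere, and with 1 such gene local and distant causes cannot be told apart. In the wider set of genes called in the strain average, the region had fewer calls, 25 of 88 (28.4%) against 41.8% elsewhere (Fisher's exact p = 0.0122, two-sided, over neighbouring genes that are not independent), which goes with local differences as part of the cause there, while the 25 calls arose where both strains carry the NOD haplotype. A difference in regulation between the strains stays open and was not tested.

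The 2nd was the smaller transgene response in NOD DN4 cells. If the NOD sort held one lower share of otherwise alike altered cells, genes up and genes down would give the same share. Genes up at least 2-fold in B6g7 gave 31.49% (30.3 to 32.9 by resampling genes, which are not independent) and genes down at least 2-fold 49.81% (48.6 to 50.9), which argues against that mixture as the whole cause. The narrow B6g7 DN4 arrays are also an unlikely whole cause, since 2496 genes were called after quantile normalization again. A different mix of cell states and an effect of strain on the response to the transgene stay open and were not tested.

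The 3rd was the excess of higher calls in the strain by stage interaction and its cell cycle genes. Within BDC arrays 77.49% of calls were higher (1305 and 379), against 81.08% within non-Tg arrays. The interval for the BDC arrays, 75.42 to 79.47, takes genes as independent, which they are not. The median of all genes was 0.05 within BDC arrays and 0.16 within non-Tg arrays. The BDC arrays keep a contrast in width of the same sign, 0.25 against 0.52 in log2 quartile ratio, so array width and biology cannot be told apart for the excess, and after quantile normalization again of all arrays 906 calls were higher and 592 lower. With the same normalization the cell cycle median fell from 0.67 to 0.5016 (0.4383 to 0.6408) and the genes called higher from 43 to 34 of 46, against a median of 0.01 for all genes, so the narrow arrays are unlikely to be its whole cause. On the values as deposited, the cell cycle median was 1.08 within BDC arrays and 0.31 within non-Tg arrays. The cell cycle shift was thus larger in BDC cells, where the contrast in width was smaller. A strain difference in proliferation at DN4, larger in BDC cells, is a candidate explanation that these data do not separate from a different mix of cycling cells.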

How the results depend on the processing

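Leaving out the male arrays, signals raised to a background level, the crossed replicate block and quantile normalization with an array left out were chosen after the data were seen. Named genes were recomputed under the alternatives other than the 2-fold minimum, the crossed replicate block and quantile normalization with an array left out. No called change reversed, 37006 results were the same, 131 became called and 1887 were lost. Most named genes were chosen for called changes in the same data, so reversals were unlikely from the start. Most of the results came from leaving out each array in turn, so the totals say little about other alternatives. With only the arrays compared, 875 were the same, 18 became called and 107 were lost. The share lost was largest without the male arrays. Gene lists were recomputed with the filters, every probe set, the replicate block, sex as a term, trended and robust eBayes, arrays left out, the male arrays left out and an estimated correlation. Of these list results 7048 were the same, 59 became called and 189 were lost, 110 of them with the estimated correlation. Of the gene counts 399 stayed within 1.5 times and 96 moved. The filters, every probe set, median centring, sex as a term, and trended and robust eBayes moved no count over 1.5 times, nor did raised signals, with which 7 named genes lost a call. Where a count moved the cause was not tested, except where the design fixes it. A 2-fold minimum lowers a count by construction. Leaving out an array of a group outside a comparison can act only through the shared estimate of the spread and its degrees of freedom.

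Quantile normalization again gave 1498 genes for strain by stage. Only the arrays compared gave 81 for strain in non-Tg DN2-3, 1505 in BDC DN2-3, 297 and 4098 for the transgene in NOD DN2-3 and DN4, and 30 and 3305 for strain by transgene in DN2-3 and DN4; it does not apply where all 16 arrays were used. Array weights gave 226, 1710 and 3012 for strain in non-Tg DN2-3, BDC DN2-3 and non-Tg DN4, 1228 and 4491 for the transgene in NOD DN2-3 and DN4, and 36 and 3436 for strain by transgene in DN2-3 and DN4. Quantile normalization with NOD DN2-3 replicate 1 left out gave 1676 and 3150 for strain in BDC DN2-3 and non-Tg DN4, 4940 for stage, and 241 and 3880 for strain by transgene in DN2-3 and DN4.

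The labels do not say that replicate numbers mark the same animals, so whether they pair the arrays stays open. Replicate differences, across genes, correlated over 0.1 in 8 of 28 pairs of groups and under -0.1 in 7. Between DN2-3 and DN4 of one strain and genotype the correlations were 0.585 in NOD, 0.27 in BDC/B6g7, 0.102 in B6g7 and 0.0888 in BDC/NOD, and replicate 1 of each BDC group is male. The replicate block moved no count over 1.5 times, the random replicate block (correlation 0.308) gave 3906 for strain by stage against 2329 without it, and the crossed replicate block 1876 for strain in non-Tg DN2-3.

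With a 2-fold minimum the counts were 125 for the strain average, 156 and 152 for strain in non-Tg and BDC DN2-3, 133 and 685 in non-Tg and BDC DN4, 263 and 773 for the transgene in DN2-3 and DN4, 277 and 339 in B6g7 and NOD DN2-3, 1665 and 278 in B6g7 and NOD DN4, 115 for stage, 58 and 457 for strain by transgene in DN2-3 and DN4, 70 for strain by stage and 1415 for transgene by stage.

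Without the 4 male arrays each BDC group has a lone array, assumed to vary like the other groups. The counts were then 2468 for the strain average, 380 and 133 for strain in non-Tg and BDC DN2-3, 417 and 1731 in non-Tg and BDC DN4, 2611 for the transgene in DN2-3, 977 and 855 in B6g7 and NOD DN2-3, 613 in NOD DN4, 1113 for stage, 4 and 321 for strain by transgene in DN2-3 and DN4, and 26 for strain by stage. The transgene in DN4 (4361), in B6g7 DN4 (4258) and by stage (4174) stayed within 1.5 times.

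Leaving out each array in turn, with the lone array of its group assumed to vary like the others, gave 3826 to 5731 for the strain average, 388 to 4742 and 447 to 1679 for strain in non-Tg and BDC DN2-3, 435 to 4379 and 3104 to 5511 in non-Tg and BDC DN4, 4247 to 6536 and 5686 to 7237 for the transgene in DN2-3 and DN4, 1625 to 4600 and 2017 to 5784 in B6g7 and NOD DN2-3, 5221 to 7221 and 1353 to 3957 in B6g7 and NOD DN4, 2327 to 4740 for stage, 56 to 2744 and 1305 to 3734 for strain by transgene in DN2-3 and DN4, 1197 to 5474 for strain by stage and 5685 to 6949 for transgene by stage. Low signal over background limits changes in weakly expressed genes, since no detection calls were given.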

Other observations

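The gene families here were chosen after the results were seen, from 15 looked at, and were not tested as sets. All 6 guanylate-binding protein genes, which interferon induces, were lower in BDC DN2-3 cells, with a median of -1.99 and Gbp8 at -2.33, and in DN4 2 were higher and 1 lower. All 8 Gimap genes, which encode GTPases of lymphocyte survival, were higher in BDC DN4 cells with a median of 1.47. Of 8 chemokine receptor genes 6 were higher in BDC DN4 cells (median 1.76) and 6 were lower in NOD on average (median -0.33). Genes with Psma, Psmb, Psmc or Psmd symbols, most of them of proteasome subunits, were higher in BDC DN2-3 cells in 31 of 38 and lower in BDC DN4 cells in 25, with medians of 0.36 and -0.37. Psmc3ip, which does not encode a subunit, is among the 38 and the 25. Mitochondrial complex I subunits were higher in 18 of 34 and lower in 28 in the same comparisons, with medians of 0.29 and -0.51. Genes of cholesterol and fatty acid synthesis and its control were higher in NOD on average in 15 of 21 (median 0.35) and lower in BDC DN4 cells in 12 (median -0.37). Each of these medians kept its sign after quantile normalization again and after centring.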
